A study of Mus musculus with 12 samples.

How the data were processed

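The submitters' processing notes name GenomeStudio without a version. Per the file headers, the intensities used here are mean bead signals per probe, deposited without background subtraction or scaling between arrays. The detection p-values, deposited beside them, compare each probe with the negative control beads of its array, per the file headers. A further deposited table of intensities on a linear scale was used only as an alternative. Its values keep the order of the signals within each array and share nearly the same distribution across arrays, so they had been normalized between arrays, and its steps are not given in the sources used here. According to the labels, RNA was isolated with Trizol and RNeasy columns and amplified to biotinylated cRNA. No file names the bead chip of an array.

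Signals were background corrected with the nec function of limma, which infers the background from the detection p-values, with an offset of 16, then quantile normalized and brought to log2. Probes took the gene symbol of the platform annotation, brought up to date by Entrez identifier for 23962 of 23978 probes with a symbol, and 1719 probes had none. A probe was kept when its detection p was under 0.01 on at least 3 of the 12 arrays (11382 probes). Each gene was read from its probe with the highest mean, which left 8420 genes, 2166 of them with further detected probes. Among called genes with further probes, all probes had the same direction for 94.1% (dex in control), 79.9% (dex in dKO), 79.8% (genotype in EtOH), 92.3% (genotype in Dex) and 75% (interaction). Being above background means a detection p under 0.01, and a group is at background when none of its 3 arrays was above it.

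A linear model with 1 mean per group was fitted over the 12 arrays with limma, and variances were moderated by empirical Bayes (11.5 degrees of freedom, 3.52 of them from the prior). The 5 comparisons were Dex against EtOH in each genotype, dKO against control under each treatment, and the interaction, which is the Dex change in dKO less that in control. All p-values of genes are from moderated t-tests with the Benjamini-Hochberg adjustment over the 8420 genes of a comparison, and a gene was called at an adjusted p under 0.05. The groups of 3 were treated as independent. Residuals of arrays with the same replicate number correlated between -0.18 and -0.05 across treatments within a genotype. Between genotypes within a treatment they correlated between -0.05 and 0.14. There the best partner had the same number for all replicates in EtOH and for replicates 2 and 3 in Dex. With 3 arrays per group this cannot decide whether the numbers pair the arrays. With the number as a replicate block the interaction was called for 37 genes, and with the block within genotype for 32. Response sizes were compared over the genes called for the average Dex effect of both genotypes, with fry from limma, whose p-values come from the same linear model. It tests the mean standardized difference of the set against 0. It does not test the median, nor the set against all genes, so a difference shared by all genes can make it pass.

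A gene at background in 1 group has no fitted fold that can be relied on. Its change is given as at least N-fold, from the mean of the other group less the mean of the group at background with each array raised to the lowest above-background value of that array (log2 6.09 to 6.35). For comparisons of 2 groups, medians of some lists are also given with such genes at these bounds. For the interaction no medians at bounds were computed.

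The 20 gene lists and 8 marker lists were written from general knowledge, with the comparisons, the thresholds, the alternatives and the rule for naming genes, before the data were examined. Lists with at least 3 measured genes, 26 in all, were tested with camera from limma at a preset correlation of 0.01 between genes, and adjusted over the 26 lists of a comparison. Where that call was lost with the correlation estimated from the residuals, this second p is given. Per1 is on both the glucocorticoid-induced and the clock output list. The lists have no independent replicates beyond the 3 arrays per group.

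The genes named are, for each comparison of 2 groups, the 10 with the largest change in each direction among called genes whose groups do not overlap (10% of genes by chance with 3 against 3), and for the interaction the 10 with the smallest p in each direction. Cry1, Cry2, Per1, Per2, Nr3c1, Fkbp5, Tsc22d3 and Sgk1 are named throughout, as are up to 4 members with the smallest p of a described list. Eif2s3y, Kdm5d, Uty and Xist belong to the marker list of embryo sex.

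The alternatives were no background correction, median scaling in place of quantile normalization, the deposited table, an offset of 50, a detection p of 0.05, no filter, all probes as separate items, eBayes with trend and robust set, array weights, only the compared groups in the fit, the replicate number as a block or within genotype as a block, a fold of at least 1.5, and each of the 12 arrays left out. After the data were seen, 2 more were added for the 3 arrays that share a shift: these 3 against the other 9 as a block, and the fit without them. The latter leaves dKO_EtOH replicate 3 as the only array of its group. Also added after the data were seen were fits with each gene kept on the probe of the reported fit, since settings that leave out arrays or change the values chose it again.

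In simulated data with known changes in the same design, the genes recovered at a 2-fold change were 70.8% (Dex in control), 69.7% (Dex in dKO), 66.2% (genotype in EtOH), 80.6% (genotype in Dex) and 41.3% (interaction). At a 4-fold change they were 89.4%, 96.8%, 90.5%, 93.8% and 80.3%, and at 1.5-fold 33.3%, 43.3%, 36.4%, 28.8% and 12.1%. Of the genes called in these data 8.63%, 5.56%, 5.34%, 5.67% and 2.25% had no simulated change, above the nominal 5% in the first 4. The simulated noise was independent between genes and held no shift shared by arrays. For the comparisons of 2 groups, fewer genes were changed than were called on the real arrays. The shares may therefore differ on the real arrays. Median differences simulated at -0.585 and 0.585 on the log2 scale were measured at -0.54 and 0.54, and a list raised by 0.50 at 0.53. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.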

Results

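Messenger RNA abundance was measured with Illumina bead arrays in primary mouse embryonic fibroblasts (MEFs), connective-tissue cells grown out of C57BL6/J embryos. The 12 arrays fell into 4 groups of 3 biological replicates: control and cryptochrome double knockout (dKO) MEFs, each given 1 µM dexamethasone (Dex, a synthetic glucocorticoid) or its ethanol vehicle (EtOH) for 16 hours. Cry1 and Cry2 encode the cryptochromes, transcriptional repressors of the circadian clock. The sample labels give the control cells as heterozygous for both genes, whereas the design text calls them wild type. They are called control here. Each array read 25697 probes, of which 10953 to 11527 (42.6% to 44.9%) were above background, and its median signal lay between 187 and 216. Levels are log2 signals after background correction and quantile normalization, changes are log2 differences with the standard error (SE) of the model, n is 3 arrays per group in the reported fit, and 8420 genes were tested. The number of arrays limits the precision. The series title names a repression of the glucocorticoid receptor by cryptochromes, so the comparisons asked what Dex does to control cells, what it does to dKO cells, whether these responses differ, and how the genotypes differ under each treatment.

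The arrays could not check the deletions themselves. The Cry1 probe was at background on all 12 arrays, controls included, with group means of 4.54 to 4.68. The Cry2 probe was above background on 10 arrays, and its mean was not lower in dKO than in control MEFs, at 6.16 ± 0.30 (SD) in control EtOH, 6.64 ± 0.18 in control Dex, 6.63 ± 0.22 in dKO EtOH and 6.77 ± 0.37 in dKO Dex. Where these probes lie relative to the deleted parts is not given in the sources used here, so neither probe checks the genotype. Nr3c1, the gene of the glucocorticoid receptor, had a probe above background on 1 array and gave no comparison. Per2, a clock repressor gene known to be repressed through cryptochromes, did separate the genotypes, at 7.18 ± 0.12 (SD) and 6.83 ± 0.24 in control EtOH and Dex and at 10.04 ± 0.15 and 10.23 ± 0.09 in dKO EtOH and Dex. Y-linked Eif2s3y and Kdm5d were above background on 12 arrays and Uty on 11, and both Xist probes were at background on all 12. In limma none of these 3 genes passed in any of the 5 comparisons, with 1 at an unadjusted p under 0.05 for Dex in control MEFs, 1 for genotype in Dex and 1 for the interaction, and their list was not called.

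In a principal component analysis of the 8420 genes, the first component (36.7% of the variance) parted the genotypes and the second (31.2%) mostly the treatments. The third component (14.9%) parted 3 arrays from the other arrays of their groups: control_Dex replicate 3 (-31.10), dKO_EtOH replicate 1 (-16.35) and dKO_EtOH replicate 2 (-14.07). Tested as an effect of its own, chosen after the values were seen, this shift was called for 2114 genes (25.1%), 752 higher and 1362 lower in the 3 arrays. Among the lists tested its median was largest for clock kinases and ligases (-0.36), collagen and matrix (-0.29), endothelial markers (-0.29), cartilage and bone markers (-0.25), neural markers (0.25) and adipogenesis (-0.23). It is given below where it bears on a list, and each count of called genes is also given without these 3 arrays. That fit leaves dKO EtOH with replicate 3 alone, so its results for comparisons that use dKO EtOH rest on that array.

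**Figure D1:**
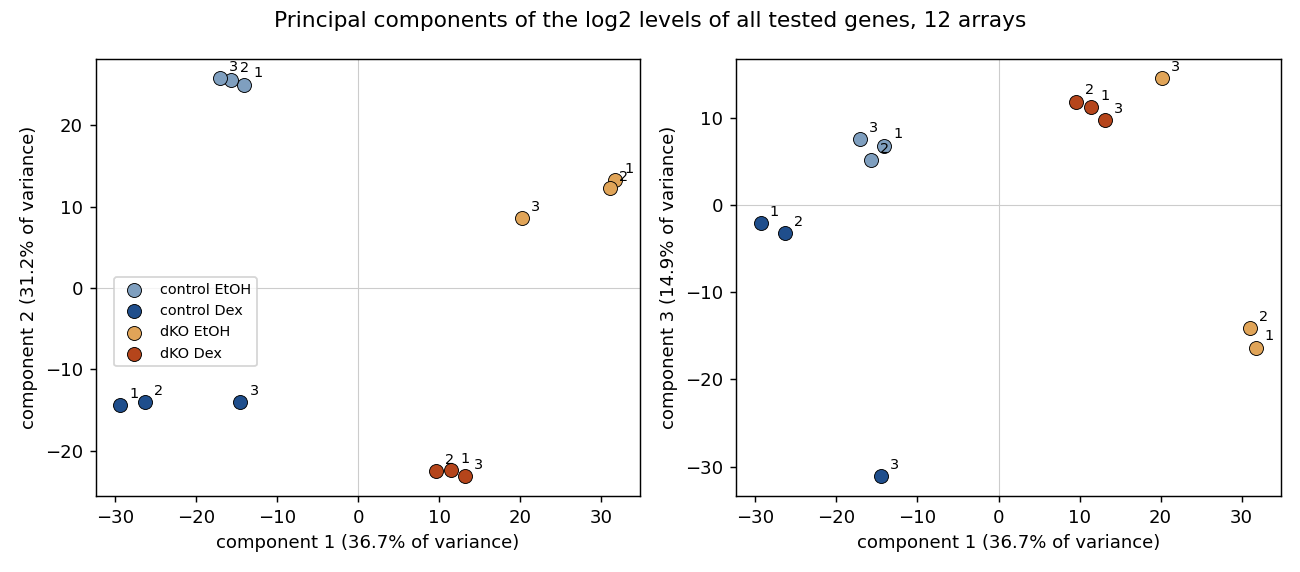
Principal component scores of the 12 arrays (components 1 and 2, and 1 and 3; axes in score units with the percent of variance), 1 point per array, coloured by group and numbered by replicate. Component 1 (36.7%) parts the genotypes and component 2 (31.2%) mostly the treatments, while component 3 (14.9%) sets control_Dex replicate 3 and dKO_EtOH replicates 1 and 2 apart.

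Dex strongly raised known glucocorticoid targets in control MEFs. Fkbp5, a co-chaperone that feeds back on the receptor, rose 22.7-fold, from 7.77 to 12.27 (change 4.50 ± 0.15). Lcn2, which encodes an iron-carrier-binding protein, was at background on every EtOH array and reached 11.43, at least 37.5-fold higher. Sult1a1, a phenol sulfotransferase, rose by 5.03 ± 0.08, Tsc22d3, an anti-inflammatory effector of glucocorticoids, by 2.36 ± 0.11, the kinase gene Sgk1 by 1.97 ± 0.10 and the clock gene Per1 by 1.76 ± 0.16. Among the largest falls were those of Ch25h, a cholesterol hydroxylase of the antiviral response (-2.81 ± 0.16), the Wnt agonist Rspo2 (-2.64 ± 0.21), the serine protease gene Prss46 (-2.62 ± 0.26), the macrophage elastase Mmp12 (-2.35 ± 0.12) and the clock output factor Dbp (-2.19 ± 0.11). In all, 1706 of 8420 genes passed an adjusted p of 0.05, 745 higher and 961 lower, and 216 and 202 of them changed at least 2-fold.

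Further genes with the largest changes included Dpep1, a membrane dipeptidase (4.08 ± 0.19), Rgcc, a cell cycle regulator (4.08 ± 0.20), and the metallothionein gene Mt2 (3.68 ± 0.25). Slc45a3, a transporter gene, was at least 10.2-fold higher, Lbp, the lipopolysaccharide-binding protein gene, at least 7.32-fold, Spink8, a protease inhibitor gene, at least 6.50-fold and Fam107a at least 5.92-fold, since their EtOH arrays were at background. On the lower side were the growth factor gene Nrg1 (-2.26 ± 0.20) and Fcrls, an Fc receptor-like gene of phagocytes (-2.23 ± 0.18). Clec7a, a receptor for fungal glucans, fell at least 4.49-fold, Ambp, a plasma protease inhibitor gene, at least 3.68-fold and Cd83, an activation marker of immune cells, at least 3.64-fold, to background in Dex.

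**Figure D2:**
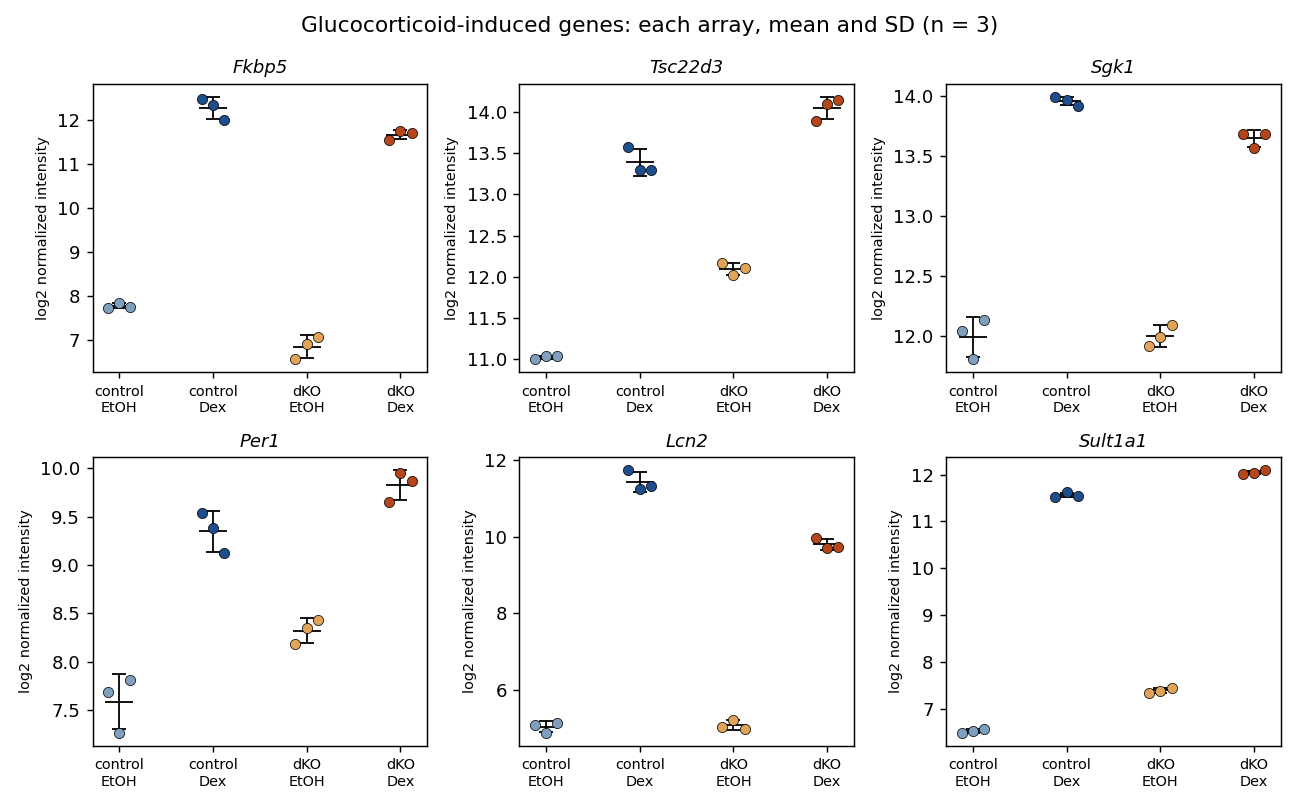
Log2 signal of 6 genes (Fkbp5, Tsc22d3, Sgk1, Per1, Lcn2 and Sult1a1) on each array, by group; points are arrays, bars are the mean ± SD of 3. Fkbp5 went from 7.77 to 12.27 in control and from 6.84 to 11.66 in dKO MEFs, and Lcn2 was at background in both EtOH groups.

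Of the lists fixed before the data were examined, the 27 measured glucocorticoid-induced genes moved most: 22 rose and 2 fell (23 and 2 adjusted over the list alone), with a median of 1.51, or 1.41 with genes at background in 1 group set at their bound (adjusted p = 1.43e-22, and 0.00463 with an estimated correlation). Of 18 inflammatory genes known to be repressed by glucocorticoids, 10 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of -0.76, or -0.49 at the bounds (adjusted p = 0.000364, and adjusted p = 0.0346 with an estimated correlation). Among them Plau, the urokinase gene, fell by 1.23 on the log2 scale (SE 0.16), the interferon regulatory factor Irf1 changed by -1.04 ± 0.13, and the cytokine gene Tnf fell at least 1.28-fold, to background. Homeobox position genes fell as a group, 8 of 11 (8 adjusted over the list alone), with a median of -0.49 (-0.50 at the bounds, adjusted p = 0.000109, and adjusted p = 0.0342 with an estimated correlation), as in Hoxb5 (-1.02 ± 0.13) and Hoxc6 (-0.82 ± 0.10). Cholesterol synthesis genes rose, 7 of 14 (9 adjusted over the list alone), among them the regulator Srebf2 (0.52 ± 0.09). Their median was 0.32 (adjusted p = 0.000278, and adjusted p = 0.0317 with an estimated correlation).

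Other lists were called with the preset correlation only. Interferon-response genes fell, 13 of 18 (15 adjusted over the list alone), with Ifit3 at -2.15 ± 0.22, Usp18 at -1.78 ± 0.23 and Irf7 at -1.37 ± 0.20. Their median was -0.72 (adjusted p = 4.46e-07, and adjusted p = 0.119 with an estimated correlation). Macrophage markers had 2 of 11 higher and 6 lower, without a call (median -0.35, adjusted p = 0.198). Of 24 cell cycle genes 10 fell and 1 rose (12 and 1 adjusted over the list alone): Mcm5, a helicase subunit, changed by -0.82 ± 0.11 and the mitotic kinase gene Aurka by -0.71 ± 0.14, while Rrm2, a ribonucleotide reductase subunit, rose by 0.84 ± 0.12. Their median was -0.40 (adjusted p = 0.00513, and adjusted p = 0.149 with an estimated correlation). Of the 4 measured genes on the list of RORE-driven and positive-arm clock genes, 3 rose (3 adjusted over the list alone). RORE are the elements bound by ROR receptors, and the list is called positive-arm below. Nfil3 rose by 1.56 ± 0.11, Arntl by 0.85 ± 0.13 and Clock by 0.54 ± 0.12. Nfil3 is RORE-driven and not of the positive arm itself. The list had a median of 0.69 (adjusted p = 0.0029, and adjusted p = 0.0748 with an estimated correlation). Of 13 hypoxia and glycolysis genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), led by Egln3, a prolyl hydroxylase (2.83-fold, 95% interval of the log2 change 1.23 to 1.77), and the peptide hormone gene Adm (0.89 ± 0.15). The list had a median of 0.17 (adjusted p = 0.00844, and adjusted p = 0.0668 with an estimated correlation), and of 0.33 without control_EtOH replicate 1 and 0.35 without control_Dex replicate 2. Of 14 smooth muscle genes 6 rose (6 adjusted over the list alone), including Ccn1 (1.11 ± 0.13), Lmod1 (0.88 ± 0.10) and Myh11 (0.79 ± 0.13). The smooth muscle list was called upwards (adjusted p = 0.0245, and adjusted p = 0.322 with an estimated correlation) with a mean of 0.24 but a median of 0.00, which was 0.17 without control_Dex replicate 3 and -0.01 without control_Dex replicate 2. Of 12 adipogenesis genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Scd1, a fatty acid desaturase, at 0.62 ± 0.11 and the lipase gene Lpl at -0.50 ± 0.11. Their median was 0.31, or 0.23 at the bounds (adjusted p = 0.0388, and adjusted p = 0.194 with an estimated correlation). This last call was lost without control_EtOH replicate 1 (0.30, adjusted p = 0.0584), control_EtOH replicate 2 (0.30, 0.0608), control_Dex replicate 1 (0.25, 0.162) or dKO_Dex replicate 2 (0.27, 0.0522), and the list had a median shift of -0.23 in the 3 arrays set apart above.

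The clock outputs driven by E-box and D-box elements moved both ways in control MEFs, and their list was not called: 3 of 11 rose and 5 fell (3 and 6 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.159). Besides Dbp, the nuclear receptor gene Nr1d2 fell by 1.63 on the log2 scale (SE 0.11) and the transcription factor gene Tef changed by -0.92 ± 0.10, whereas Per1 rose. Per2 changed by -0.35 ± 0.13, which did not pass (adjusted p = 0.0882) but did without the 3 arrays set apart above (-0.49, adjusted p = 0.0112, on the same probe), with median scaling (-0.45, adjusted p = 0.0463) and with array weights (-0.42, adjusted p = 0.00546), nor did Cry2, at 0.48 ± 0.20 (adjusted p = 0.121, and 0.0411 with array weights). Immediate early and stress genes were also split, with 4 of 20 higher and 7 lower (5 and 9 adjusted over the list alone, median -0.20, adjusted p = 0.411), Fos at 1.56 ± 0.11, the heat shock gene Hspb1 at 1.02 ± 0.14 and Egr2 at -1.09 ± 0.17. Hormone and growth factor genes had 2 of 17 higher and 6 lower (2 and 8 adjusted over the list alone, median -0.41, adjusted p = 0.116), among them Igf1 (-1.09 ± 0.11), Igfbp5 (-1.08 ± 0.11) and Igfbp6 (1.43 ± 0.13), genes of insulin-like growth factor 1 and its binding proteins. Without the 3 arrays set apart above, 1961 genes passed in control MEFs. Scaling arrays to a common median in place of quantile normalization moved the median of all genes from -0.04 to -0.15 and gave 482 genes higher and 1312 lower.

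In dKO MEFs, Dex raised the same kind of genes. Fkbp5 rose 28.2-fold, from 6.84 to 11.66 (4.82 ± 0.15), Sult1a1 by 4.65 ± 0.08, Serpina3n, an acute-phase protease inhibitor gene, by 4.53 ± 0.15 and Mt2 by 4.27 ± 0.25. Tsc22d3 rose by 1.95 ± 0.11, Sgk1 by 1.65 ± 0.10 and Per1 2.83-fold (95% interval of the log2 change 1.16 to 1.85), and Lcn2 went from background to 9.80, at least 12.5-fold higher. The largest falls were those of Mmp12 (-3.21 ± 0.12), Ch25h (-2.54 ± 0.16), the synaptic adhesion gene Lrrn3 (-2.16 ± 0.19), the peptide transporter gene Slc15a3 (-2.14 ± 0.16) and the chemokine gene Cxcl12 (-2.07 ± 0.41, adjusted p = 0.00597, and -1.01 without the 3 arrays). In all, 1230 genes passed, 726 higher and 504 lower, and 197 and 96 of them changed at least 2-fold. Median scaling moved the median of all genes from 0.03 to 0.14 and gave 871 genes higher and 343 lower.

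Also among the largest rises in dKO MEFs were Rgcc (4.09 ± 0.20), Slc45a3 (4.08 ± 0.22), Dpep1 (3.56 ± 0.19), the small heat shock gene Hspb7 (3.32 ± 0.29) and Fam107a, at least 6.47-fold higher. The secreted matrix gene Spon2 (-2.06 ± 0.13) and the chemokine gene Ccl12 (-1.93 ± 0.13) fell, and Clec7a, AW551984 and Ambp fell to background, at least 2.70-fold, 2.31-fold and 2.27-fold. Cry2 (0.14 ± 0.20, adjusted p = 0.679) and Per2 (0.19 ± 0.13, adjusted p = 0.351) did not pass.

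The glucocorticoid-induced list rose in dKO MEFs as well, with 21 of 27 higher and 1 lower (24 and 1 adjusted over the list alone) and a median of 1.04, unchanged at the bounds (adjusted p = 1.14e-22, and adjusted p = 0.00456 with an estimated correlation). Of the 18 inflammatory genes 11 fell (11 adjusted over the list alone), with a median of -0.59, or -0.46 at the bounds (adjusted p = 6.73e-06, and adjusted p = 0.018 with an estimated correlation), including the collagenase gene Mmp13 (-0.98 ± 0.13) and the monocyte chemoattractant gene Ccl2 (-1.53 ± 0.20). The cytokine gene Il6 fell at least 1.39-fold, to background. The lists that follow were called with the preset correlation only. Immediate early and stress genes fell, 9 of 20, while 2 rose (10 and 2 adjusted over the list alone). Nqo1, a quinone reductase, changed by -1.44 ± 0.20, while Fos (1.62 ± 0.11) and Hspb1 (1.17 ± 0.14) rose. Their median was -0.29 (adjusted p = 0.00714, and adjusted p = 0.152 with an estimated correlation). Smooth muscle genes had 4 of 14 higher (6 adjusted over the list alone), among them Myh11 (1.03 ± 0.13), Lmod1 (0.83 ± 0.10) and the myosin kinase gene Mylk (0.65 ± 0.13). Their median was 0.23 (adjusted p = 0.0107, and adjusted p = 0.218 with an estimated correlation). Without the 3 arrays set apart above the call was lost (0.13, adjusted p = 0.0698), and the median was 0.15 without dKO_EtOH replicate 1 and 0.35 without dKO_EtOH replicate 3. Hormone and growth factor genes had 5 of 17 lower and 1 higher (7 and 1 adjusted over the list alone), with Igf1 at -1.24 ± 0.11. The list had a median of -0.25 (adjusted p = 0.0148, and adjusted p = 0.107 with an estimated correlation), and of -0.07 without dKO_EtOH replicate 3 and -0.45 without the 3 arrays.

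The remaining 3 calls in dKO MEFs were weak. Interferon-response genes had 2 of 18 lower (2 adjusted over the list alone), with a median of -0.23 that was -0.08 at the bounds (adjusted p = 0.0393, and adjusted p = 0.415 with an estimated correlation), with Ifit3 at -1.08 ± 0.22 (without the 3 arrays -0.78, adjusted p = 0.169). Cell cycle genes had 4 of 24 lower and 1 higher (4 and 1 adjusted over the list alone), with the topoisomerase gene Top2a at -1.02 ± 0.19 and Rrm2 at 0.94 ± 0.12. Their median was -0.15 (adjusted p = 0.0408, and adjusted p = 0.23 with an estimated correlation). Hypoxia and glycolysis genes had 5 of 13 higher (6 higher and 2 lower adjusted over the list alone), with Egln3 at 1.55 ± 0.12 and Adm at 0.90 ± 0.15. Their median was 0.21 (adjusted p = 0.0494, and adjusted p = 0.163 with an estimated correlation). Without the 3 arrays the interferon median was -0.09 (adjusted p = 0.745) and the cell cycle median -0.16 (adjusted p = 0.321). Single arrays also ended these calls. For interferon they were dKO_EtOH replicates 1 (-0.27, adjusted p = 0.0885) and 2 (-0.22, 0.0699) and dKO_Dex replicate 1 (-0.27, 0.0782), with -0.35 without dKO_EtOH replicate 3. For cell cycle they were dKO_EtOH replicate 2 (-0.16, 0.112) and dKO_Dex replicates 2 (-0.15, 0.0618) and 3 (-0.17, 0.0918), with -0.23 without dKO_Dex replicate 1. The hypoxia call ended without any of control_EtOH replicates 1 to 3 (0.20, 0.21 and 0.21, adjusted p = 0.0571, 0.0561 and 0.0575), control_Dex replicate 3 (0.20, 0.0529), dKO_EtOH replicate 3 (0.19, 0.141) or dKO_Dex replicates 2 (0.20, 0.0618) and 3 (0.22, 0.0814).

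Lists without a call for Dex in dKO MEFs included cholesterol synthesis (5 of 14 higher, 6 adjusted over the list alone, median 0.24, adjusted p = 0.0554), with Lss, the lanosterol synthase gene, at 1.06 ± 0.14, and homeobox genes (3 of 11 lower, median -0.10, adjusted p = 0.211). Neither were the clock lists called: outputs had 3 of 11 higher and 1 lower (4 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.179), with Dbp at -0.49 ± 0.11 (not past the test without the 3 arrays, -0.50, adjusted p = 0.0726, or with median scaling, -0.30, adjusted p = 0.15). Of the positive-arm list only Nfil3 rose (1.23 ± 0.11), with a list median of 0.08 (adjusted p = 0.432). The count of 1230 genes was 684 without the 3 arrays. It was 777, 717 and 2205 without dKO_EtOH replicates 1, 2 and 3, and 801, 786 and 772 without dKO_Dex replicates 1, 2 and 3.

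The responses of the 2 genotypes shared many genes. Of the genes called in each, 379 rose in both, against 64.2 by independence, and 278 fell in both, against 57.5, and 16 went opposite ways. Without the 3 arrays set apart above, 284 rose and 216 fell in both. Across the 8420 genes the responses had a Pearson correlation of 0.56 and a Spearman correlation of 0.31, and genes are not independent replicates. A call in 1 genotype was not by itself a difference: of 366 genes called higher in control and not higher in dKO MEFs, 49 passed the test of the difference between responses, and of 683 called lower in control and not lower in dKO MEFs, 58 did. Both sets include genes called in opposite directions. That test, the interaction, passed for 193 genes, of which 108 had a more positive change in dKO MEFs (51 of them called in control only, 30 in dKO only) and 85 a more negative one (40 and 18). With median scaling it passed for 596 and 101 genes.

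Some of these differences were large. Defb1, an antimicrobial peptide gene, was at background in control MEFs (4.76 in EtOH and 4.98 in Dex) and went from background (5.91) to 8.70 in dKO MEFs, a fitted difference of 2.57 ± 0.19. Ramp2, a receptor-modifying protein gene, went from 7.02 to 7.58 and from 7.31 to 10.45 (2.59 ± 0.28), and Gsta3, a glutathione transferase gene, from 8.56 to 9.09 and from 8.11 to 10.78 (2.14 ± 0.20). In the other direction, Anxa8, an annexin gene, went from 9.38 to 12.45 in control and from 10.09 to 10.84 in dKO MEFs (-2.32 ± 0.18), and Jaml, an adhesion molecule gene, from background (5.64) to 8.81 and from background (5.71) to 6.08 (fitted difference -2.80 ± 0.29). Lcn2 and Spink8 reached lower levels in dKO than in control MEFs under Dex, 9.80 against 11.43 and 6.92 against 8.90.

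Clock outputs and interferon-response genes were the lists with the smallest adjusted p for a difference in response. Of the clock outputs, 4 of 11 genes had a more positive change in dKO MEFs (8 adjusted over the list alone). The median difference was 0.54 (adjusted p = 0.000991, and adjusted p = 0.171 with an estimated correlation), and 0.60 without dKO_EtOH replicate 3 and 0.44 without the 3 arrays with each gene kept on its probe. Dbp went from 12.38 to 10.19 in control and from 13.70 to 13.21 in dKO MEFs (1.70 ± 0.15), and Nr1d2 from 8.44 to 6.81 and from 9.58 to 9.30 (1.35 ± 0.16). Of the interferon-response genes, 1 of 18 was called, with the same sign (10 adjusted over the list alone), and the median was 0.68 (adjusted p = 0.000991, and adjusted p = 0.367 with an estimated correlation). With Dex in dKO MEFs 3 of these genes were at background in at least 1 group, so levels near background can affect this difference. No homeobox gene of 11 was called by limma (5 more positive adjusted over the list alone, 6 at an unadjusted p under 0.05), with a median of 0.47 (adjusted p = 0.00465, and adjusted p = 0.171 with an estimated correlation). The positive-arm clock genes had a median of -0.46 (0 of 4 called, 2 lower adjusted over the list alone and at an unadjusted p under 0.05, adjusted p = 0.00848, and adjusted p = 0.193 with an estimated correlation). Each of these last 3 calls was lost without dKO_EtOH replicate 3, with medians of 0.63, 0.56 and -0.42 and an adjusted p of 0.0556 for each, and the homeobox median was 0.28 without the 3 arrays set apart above. Adipogenesis genes had a median of -0.29 (0 of 12 called, 1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05, adjusted p = 0.0379, and adjusted p = 0.28 with an estimated correlation). This call ended in 8 alternative settings, among them leaving out control_EtOH replicate 2 (-0.21), control_Dex replicates 1 (-0.08) and 2 (-0.30), dKO_EtOH replicate 3 (-0.23) and dKO_Dex replicates 1 (-0.29) and 3 (-0.25). No inflammatory gene of 18 was called (1 higher and 2 lower adjusted over the list alone, 3 and 4 at an unadjusted p under 0.05, median 0.03, adjusted p = 0.728).

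Known glucocorticoid targets did not respond more strongly as a group in dKO MEFs. Of the 27 glucocorticoid-induced genes, 1 had a more positive and 3 a more negative change (1 and 5 adjusted over the list alone), among them Lcn2 (-1.67 ± 0.20) and Aqp1, a water channel gene (-1.40 ± 0.19). The median was -0.26 (adjusted p = 0.0498, and adjusted p = 0.45 with an estimated correlation), but 0.07 after median scaling, and 12 alternative settings ended the call. Single arrays that did so were control_EtOH replicate 2 (-0.18), control_Dex replicates 1 (-0.08) and 2 (-0.24), dKO_EtOH replicates 2 (-0.24) and 3 (-0.18) and dKO_Dex replicate 1 (-0.18), and without dKO_Dex replicate 3 the median was -0.13. The difference in response did not pass for Fkbp5 (0.32 ± 0.21), Tsc22d3 (-0.41 ± 0.15), Sgk1 (-0.32 ± 0.14), Per1 (-0.26 ± 0.22), Per2 (0.54 ± 0.19) or Cry2 (-0.34 ± 0.29), with adjusted p from 0.132 to 0.511, although Per2 passed with median scaling (0.78, adjusted p = 0.0425) and with array weights (0.69, adjusted p = 0.00847). Over the 968 genes called higher with Dex on average, the responses had a median of 0.53 in control and 0.54 in dKO MEFs, and the median difference was -0.01, not past the fry test. Less the median difference of all genes (0.08) it was -0.09, and it was below 0 in every setting run for it but array weights (0.06) and without dKO_EtOH replicate 3 (0.04). The median difference itself was -0.10 with the 3 arrays as a block, past the test. It was -0.09 without them, a fit that leaves dKO_EtOH replicate 3 as the only array of its group. Without dKO_EtOH replicate 3 it was 0.14, past the test in the other direction. Over the 1035 genes called lower on average the medians were -0.56 and -0.38 and the median difference 0.21, past the fry test, which less that of all genes was 0.13. Relative to all genes the medians of both sets were thus smaller in size in dKO MEFs, a comparison not tested, except with array weights, and for induced genes without dKO_EtOH replicate 3. The number of 193 interaction genes was 67 without the 3 arrays. Without control_EtOH replicates 1, 2 and 3 it was 42, 43 and 30, without control_Dex replicates 1 and 3 it was 112 and 100, without dKO_EtOH replicates 1, 2 and 3 it was 57, 57 and 1202, and without dKO_Dex replicates 1, 2 and 3 it was 50, 39 and 43.

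**Figure D3:**
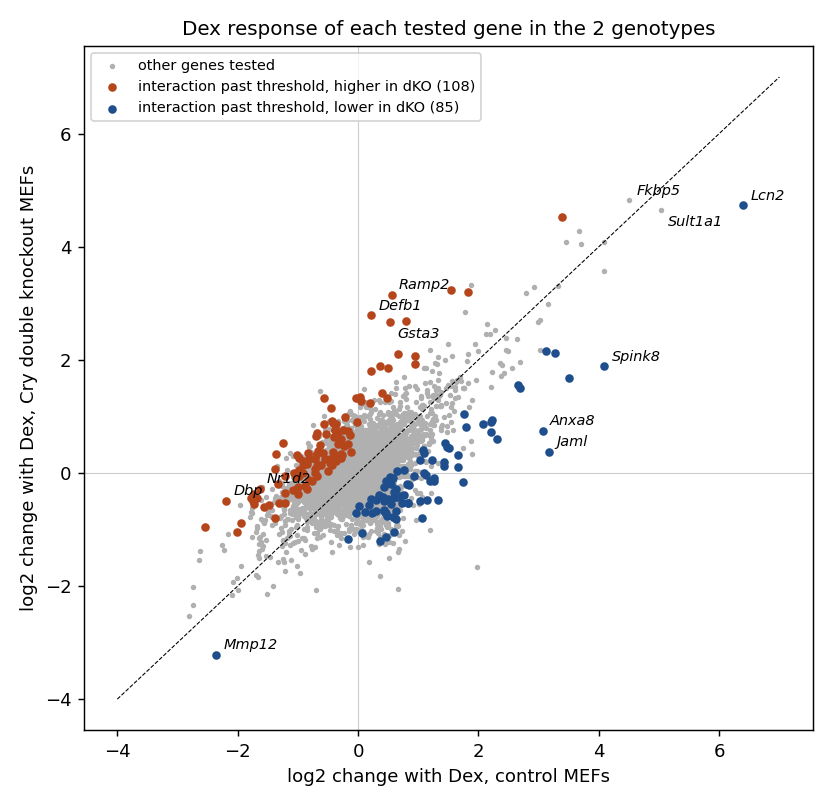
Log2 change with Dex in control (x axis) and in dKO MEFs (y axis), 1 point per gene for 8420 genes, with the 193 interaction genes coloured by direction and named examples. The points follow the diagonal (Pearson 0.56), with Anxa8 and Jaml below it and Ramp2 and Defb1 above it.

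Between genotypes in EtOH, several clock genes were higher in dKO MEFs. Per2 was higher by 2.86 ± 0.13, Ciart, another clock repressor gene, by 2.92 ± 0.12, Dbp by 1.32 ± 0.11, Nr1d2 by 1.14 ± 0.11 and Per1 by 0.73 ± 0.16 (adjusted p = 0.00536), while Arntl, the partner of Clock, was lower (-1.27 ± 0.13). The largest differences were those of the glutamate transporter gene Slc1a3 (4.99 ± 0.18) and the retinol and alcohol dehydrogenase gene Adh7 (4.32 ± 0.13). The mesothelial and kidney transcription factor gene Wt1 was at background in dKO EtOH and 9.53 in control, at least 10.4-fold lower. In all, 2234 genes passed, 903 higher and 1331 lower in dKO MEFs, 198 and 312 of them at least 2-fold.

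Of the genes with the largest differences in EtOH, the water channel gene Aqp5 (2.98 ± 0.26), Xlr4a (2.95 ± 0.16) and the ion pump regulator gene Fxyd6 (2.88 ± 0.18) were higher. Comp, a cartilage matrix gene, was at least 9.12-fold higher, the chemokine gene Cxcl15 at least 7.05-fold and Vit, vitrin, at least 4.26-fold, all from background in control. Lower were the interferon-induced genes Usp18 (-2.67 ± 0.23) and Rsad2 (-2.64 ± 0.27), the bone morphogenetic protein regulator Bmper (-2.62 ± 0.17), the homeobox gene Gsc (-2.52 ± 0.16), Ly86, a partner of a Toll-like receptor in macrophages and B cells (-2.45 ± 0.17), and the amino acid transporter gene Slc7a8 (-2.43 ± 0.25). Rnase2a, Napsa and Rpp25 were at background in dKO EtOH, at least 4.76-fold, 3.57-fold and 3.33-fold lower. Of the glucocorticoid targets named throughout, Tsc22d3 was higher by 1.07 ± 0.11 and Fkbp5 lower (-0.92 ± 0.15), and Sgk1 (0.01 ± 0.10, adjusted p = 0.971) and Cry2 (0.47 ± 0.20, adjusted p = 0.105, and 0.0493 with array weights) did not pass.

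**Figure D4:**
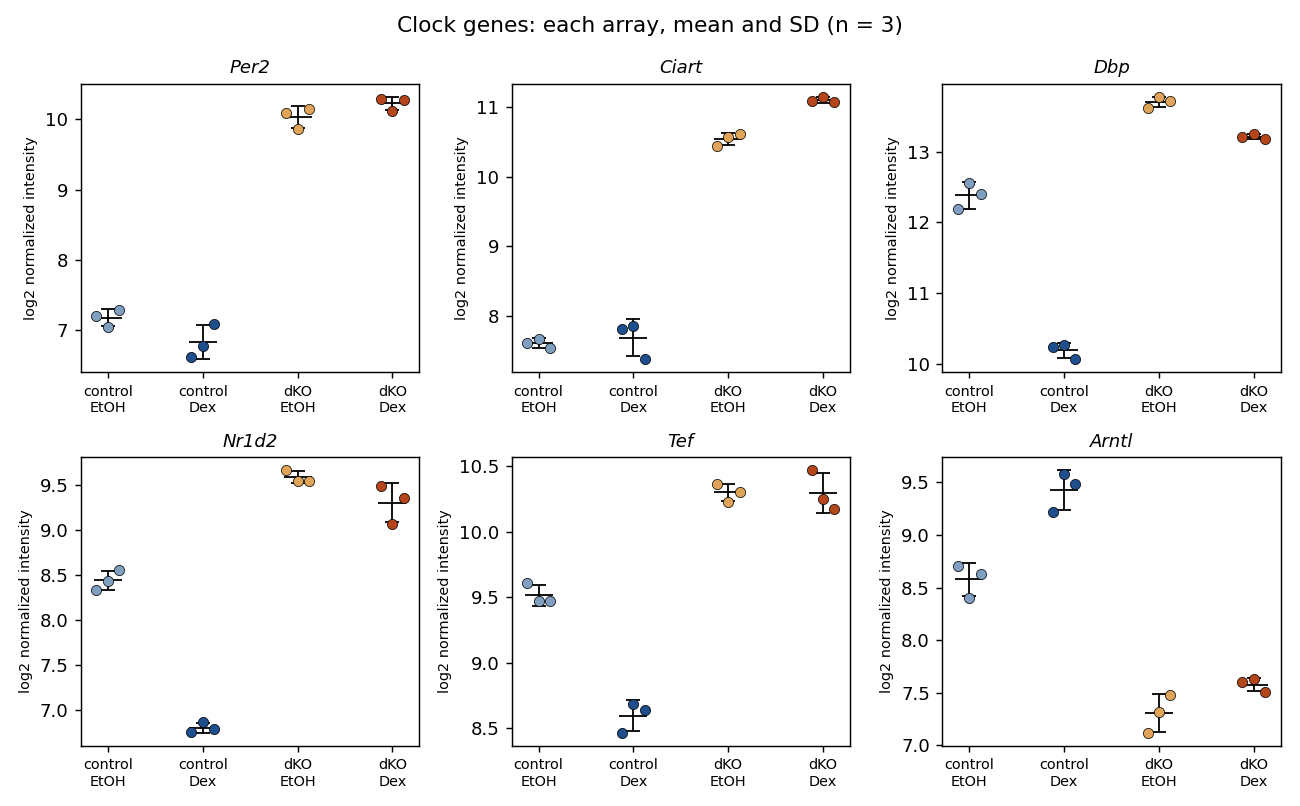
Log2 signal of 6 clock genes (Per2, Ciart, Dbp, Nr1d2, Tef and Arntl) on each array, by group; points are arrays, bars are the mean ± SD of 3. Per2 and Ciart lie higher in dKO than in control MEFs under both treatments, and Dbp goes from 12.38 to 10.19 with Dex in control MEFs and from 13.70 to 13.21 in dKO MEFs.

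Clock outputs were higher in dKO MEFs in EtOH as a list, 8 of 11 and 1 lower (9 and 1 adjusted over the list alone). Their median was 0.73, or 0.76 at the bounds (adjusted p = 8.38e-06, and adjusted p = 0.0249 with an estimated correlation). Cartilage and bone markers were higher as well, 4 of 5 (5 adjusted over the list alone), with Col2a1, the main cartilage collagen, at 2.45 ± 0.20 and the osteoblast factor Sp7 at 1.75 ± 0.23. Their median was 1.75 (adjusted p = 3.86e-05, and adjusted p = 0.0249 with an estimated correlation). This list had a median shift of -0.25 in the 3 arrays set apart above. The lists that follow were called with the preset correlation only. Interferon-response genes were lower, 12 of 18 (15 adjusted over the list alone), among them Psmb9, an immunoproteasome subunit (-1.38 ± 0.14). Their median was -1.18, or -1.11 at the bounds (adjusted p = 1.89e-07, and adjusted p = 0.129 with an estimated correlation). Macrophage markers were lower, 9 of 11 (9 adjusted over the list alone), among them Cd14 (-0.99 ± 0.13), Laptm5 (-0.92 ± 0.09) and Adgre1 (-0.88 ± 0.12). Their median was -0.63 (adjusted p = 0.000123, and adjusted p = 0.129 with an estimated correlation). Of 24 cell cycle genes 16 were lower and 1 higher (16 and 1 adjusted over the list alone), with Mcm5 at -0.96 ± 0.11 and the replication licensing gene Cdt1 at -0.88 ± 0.12. Their median was -0.47 (adjusted p = 0.000482, and adjusted p = 0.129 with an estimated correlation). Hormone and growth factor genes had 9 of 17 higher and 2 lower (9 and 2 adjusted over the list alone), with Igfbp6 at 1.78 ± 0.13, the bone morphogenetic protein gene Bmp4 at 1.11 ± 0.14 and Fgf10 at 1.01 ± 0.11. Their median was 0.51 (adjusted p = 0.00253, and adjusted p = 0.052 with an estimated correlation).

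Lists without a call in EtOH included glucocorticoid-induced genes (7 of 27 higher and 5 lower; 9 and 6 adjusted over the list alone, median 0.04, or 0.18 at the bounds, adjusted p = 0.159) and inflammatory genes (4 of 18 higher and 3 lower; 4 and 4 adjusted over the list alone, median -0.20 against a mean of 0.03, adjusted p = 0.878), with the proteinase genes Mmp3 (1.79 ± 0.13) and Mmp13 (1.75 ± 0.13) higher. Homeobox genes had 2 of 11 higher and 6 lower (2 and 6 adjusted over the list alone, median -0.36, adjusted p = 0.159), with Hoxa7 at -1.17 ± 0.12, Hoxa5 at -1.16 ± 0.10 and Hoxc6 at -1.12 ± 0.10. The count of 2234 genes was 1414 without the 3 arrays, 1442 without control_EtOH replicate 3 and 1452 without dKO_EtOH replicate 2. Median scaling moved the median of all genes from -0.05 to -0.25 and gave 518 genes higher and 2589 lower.

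Between genotypes in Dex, Per2 was higher in dKO MEFs by 3.40 ± 0.13, Ciart by 3.40 ± 0.12, Dbp by 3.02 ± 0.11 and Nr1d2 by 2.49 ± 0.11, and Arntl was lower (-1.85 ± 0.13). Adh7 (5.01 ± 0.13), the aldehyde dehydrogenase gene Aldh3a1 (4.25 ± 0.30) and Aqp5 (3.68 ± 0.26) were higher, as were Slc1a3, at least 18.9-fold, Comp, at least 10.7-fold, Fxyd6, at least 7.26-fold, Vit, at least 5.87-fold, and Defb1, at least 5.74-fold, each from background in control Dex. Wt1 was lower (-3.45 ± 0.13), as were Jaml (-2.73 ± 0.21), the bladder epithelium gene Upk1b (-2.46 ± 0.19), Dlk1, an inhibitor of fat cell differentiation (-2.14 ± 0.27), the transcription factor gene Klf5 (-2.14 ± 0.28), Fam180a (-2.09 ± 0.17) and Slc15a3 (-2.06 ± 0.16). The mean of Jaml in dKO Dex lay near background, so the size of its difference is uncertain. Napsa, Sirpb1a and Arg1 were at background in dKO Dex, at least 5-fold, 2.72-fold and 1.82-fold lower. In all, 1662 genes passed, 835 higher and 827 lower, 210 and 152 of them at least 2-fold.

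Of the genes called in both treatments, 405 were higher and 510 lower in dKO MEFs in each, against 89.5 and 131 by independence, and 32 had opposite signs. Tsc22d3 was higher in Dex by 0.66 ± 0.11 and Fkbp5 lower (-0.61 ± 0.15, adjusted p = 0.0137), a call lost without control_Dex replicate 1 (adjusted p = 0.054) or dKO_Dex replicate 1 (adjusted p = 0.0557). Per1 (0.48 ± 0.16, adjusted p = 0.0527), Sgk1 (-0.31 ± 0.10, adjusted p = 0.0505) and Cry2 (0.13 ± 0.20, adjusted p = 0.72) did not pass. Per1 passed without control_EtOH replicate 2 (0.48, adjusted p = 0.029), control_Dex replicate 1 (0.57, 0.0446) or dKO_EtOH replicate 3 (0.48, 0.05), and Sgk1 without control_EtOH replicate 2 (-0.31, 0.0351) or dKO_EtOH replicate 3 (-0.31, 0.0426). Processing decided these calls too: both genes passed without background correction (adjusted p = 0.0162 for Per1 and 0.0221 for Sgk1), in the deposited table (0.0188 and 0.0185), with an offset of 50 (0.0356 and 0.0445), with trend and robust variances (0.0439 and 0.0223) and with array weights (0.0255 and 0.013), and Sgk1 also with the 3 arrays as a block (0.0223).

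Clock outputs were again higher in Dex as a list, 7 of 11 (9 adjusted over the list alone; median 1.46, adjusted p = 1.73e-09, and adjusted p = 0.00889 with an estimated correlation), and so were cartilage and bone markers, 4 of 5 (4 adjusted over the list alone; median 1.56, adjusted p = 0.000169, and adjusted p = 0.0374 with an estimated correlation). The cartilage median was 0.50 at the bounds, since 3 of the 5 genes were at background in control Dex. The other calls held with the preset correlation only. Macrophage markers were lower, 8 of 11 (9 adjusted over the list alone), with the complement gene C1qc at -0.91 ± 0.13 and Fcer1g at -0.77 ± 0.11. Their median was -0.65 (adjusted p = 7.47e-06, and adjusted p = 0.0974 with an estimated correlation). Interferon-response genes had 9 of 18 lower and 1 higher (11 and 1 adjusted over the list alone), with Usp18 at -1.58 ± 0.23. Their median was -0.61, or -0.45 at the bounds (adjusted p = 0.000537, and adjusted p = 0.288 with an estimated correlation). Cell cycle genes had 9 of 24 lower and 1 higher (14 and 1 adjusted over the list alone), with the cyclin gene Ccnd1 at 0.84 ± 0.11 and the ribonucleotide reductase gene Rrm1 at -0.65 ± 0.10. Their median was -0.37, or -0.36 at the bounds (adjusted p = 0.00104, and adjusted p = 0.131 with an estimated correlation). Hormone and growth factor genes had 8 of 17 higher and 2 lower (8 and 2 adjusted over the list alone), with Igfbp4 at 1.66 ± 0.09 and Igf1 at -0.73 ± 0.11. Their median was 0.53, or 0.25 without control_Dex replicate 3 (adjusted p = 0.0109, and adjusted p = 0.0974 with an estimated correlation). Adipogenesis genes had 3 of 12 lower and 1 higher (5 and 1 adjusted over the list alone), with the lipid droplet gene Plin2 at -1.22 ± 0.17 and Lpl at -0.77 ± 0.11. Their median was -0.38 (adjusted p = 0.0377, and adjusted p = 0.27 with an estimated correlation). The call was lost without control_Dex replicate 1 (-0.26, adjusted p = 0.0665) or dKO_Dex replicate 1 (-0.29, 0.0638) or 3 (-0.25, 0.0613). The glucocorticoid-induced (6 of 27 higher and 4 lower, median -0.03), inflammatory (2 of 18 higher and 5 lower, median -0.05) and homeobox lists (3 of 11 higher and 4 lower, median 0.27, or 0.19 at the bounds) were not called in Dex (adjusted p = 0.929, 0.947 and 0.935). Adjusted over each list alone, 7, 3 and 5 of their genes were higher and 5, 6 and 4 lower. Without the 3 arrays set apart above, 2361 genes passed between genotypes in Dex, and with median scaling 763 were higher and 695 lower.

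**Figure D5:**
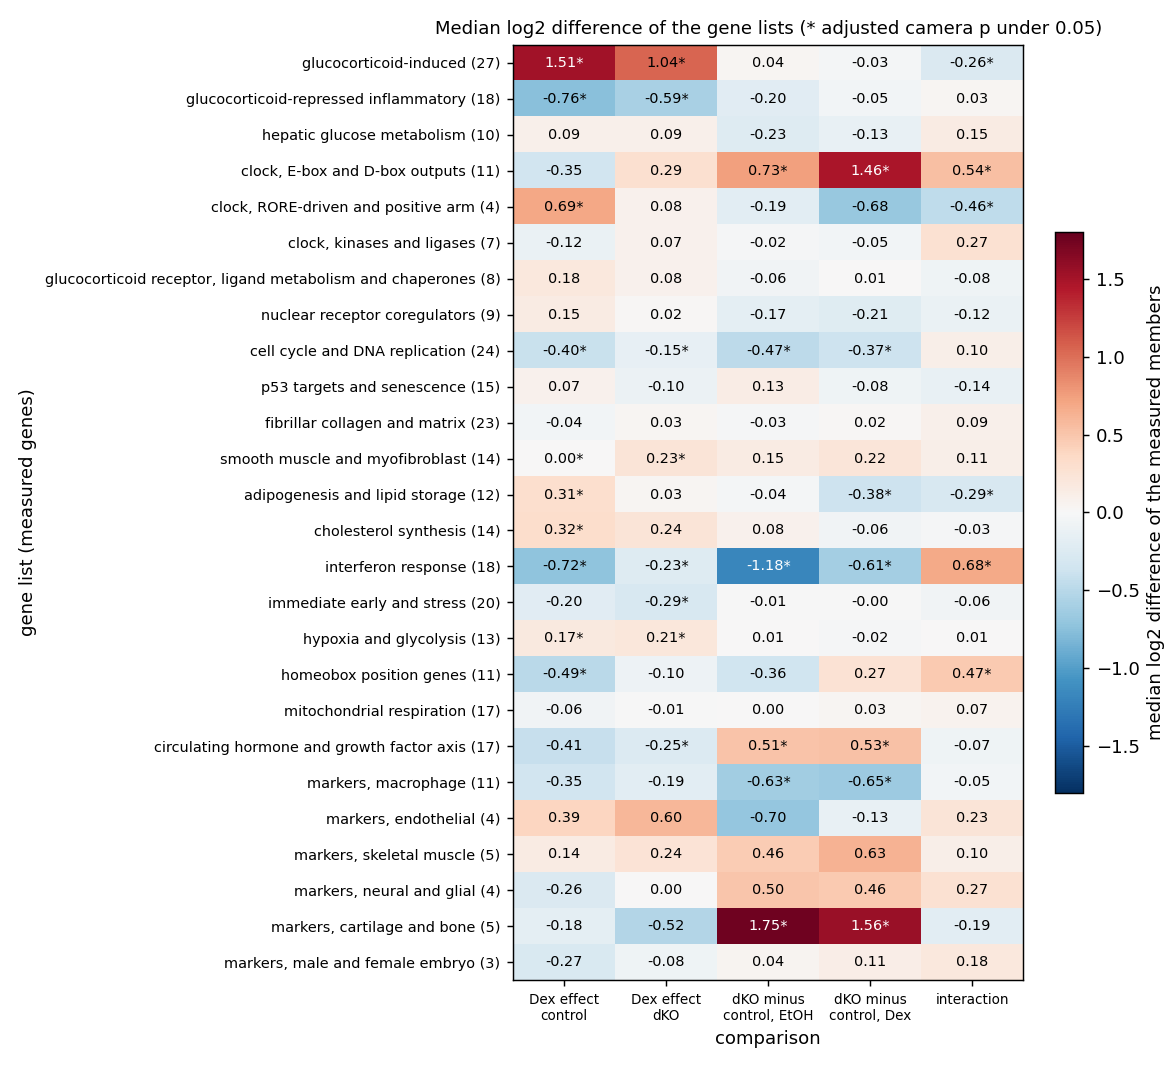
Median log2 change of each gene list (y axis, with its number of measured genes) in the 5 comparisons (x axis), printed and coloured by size, with an asterisk where the adjusted p with the preset correlation was under 0.05. Glucocorticoid-induced genes lie at 1.51 and 1.04 with Dex in control and dKO MEFs, and cartilage and bone markers at 1.75 and 1.56 between genotypes in EtOH and Dex.

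Some lists were called in no comparison. They are given in the order of Dex in control MEFs, Dex in dKO MEFs, genotype in EtOH, genotype in Dex and the interaction. The 17 measured genes of mitochondrial respiration had 0 called by limma in each comparison, with 1, 0, 1, 1 and 1 at an unadjusted p under 0.05 in the order given above, and medians from -0.06 to 0.07. Collagen and matrix genes, 23 measured, had medians between -0.04 and 0.09, although with Dex in control MEFs 4 rose and 5 fell (5 and 5 adjusted over the list alone), among them Lox, a collagen cross-linking enzyme (1.22 ± 0.11), and Dcn, decorin (-1.28 ± 0.16). Genes of the receptor's ligand metabolism and chaperones, 8 measured, had 3 higher and 1 lower with Dex in control MEFs (3 and 1 adjusted over the list alone, median 0.18), with H6pd, which supplies the reductant for cortisol regeneration, at 1.19 ± 0.17. Their other medians were 0.08, -0.06, 0.01 and -0.08. The medians were 0.15, 0.02, -0.17, -0.21 and -0.12 for 9 nuclear receptor coregulators, 0.07, -0.10, 0.13, -0.08 and -0.14 for 15 targets of p53, and -0.12, 0.07, -0.02, -0.05 and 0.27 for 7 clock kinases and ligases. For 10 genes of hepatic glucose metabolism they were 0.09, 0.09, -0.23, -0.13 and 0.15, and the glucose transporter gene Slc2a1 rose with Dex by 0.77 ± 0.12 in dKO MEFs. At the bounds the hepatic medians were 0.03 with Dex in control, 0.07 with Dex in dKO MEFs and -0.27 for genotype in EtOH. Of these lists' genes, 2 p53 targets rose with Dex in control MEFs, Trp53inp1 by 0.72 ± 0.11 and Pmaip1, a mediator of apoptosis, by 1.40 ± 0.22. The macrophage marker list, called above between genotypes, was not called with Dex in dKO MEFs, with 1 of 11 higher and 2 lower (median -0.19, adjusted p = 0.117). Endothelial markers, 4 measured, had medians of 0.39, 0.60, -0.70, -0.13 and 0.23, skeletal muscle markers, 5 measured, of 0.14, 0.24, 0.46, 0.63 and 0.10, and neural and glial markers, 4 measured, of -0.26, 0.00, 0.50, 0.46 and 0.27. In neural markers with Dex in control MEFs the mean was 0.24, against the sign of the median, since the dendrite gene Map2 rose by 2.27 ± 0.14. Of the epithelial markers 2 were measured and the list was not tested, and no erythroid marker was measured.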

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

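Of the tests in this part, those on other splits of the arrays, on further probes and on neighbours of the targeted loci were chosen before their results were seen, and all others after, among them the splits with the average genotype difference taken out; the test on bright genes was specified again after a first version had been run.

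The Dex response differed between genotypes, by a test of the interaction, for 193 genes and for the set of genes that fell with Dex on average (median 0.21). It also differed for 6 lists: glucocorticoid-induced genes (-0.26), clock outputs (0.54), positive-arm clock genes (-0.46), adipogenesis (-0.29), interferon response (0.68) and homeobox genes (0.47). All of these list calls held with the preset correlation only (adjusted p from 0.171 to 0.45 with an estimated correlation). The genes with the smallest p and a more positive response in dKO MEFs were Defb1 (2.57), Dbp (1.70), Gsta3 (2.14), Rnase2a (1.44), Rpp25 (1.88), Ramp2 (2.59), the troponin gene Tnnt1 (1.59), Il16 (1.22), Nr1d2 (1.35) and Pdlim4 (1.24). Those with a more negative response were Spink8 (-2.21), Anxa8 (-2.32), Jaml (-2.80), Tinagl1 (-1.55), Rab15 (-1.48), Stard10 (-1.37), Lcn2 (-1.67), Trpc4 (-1.34), Kif3b (-1.45) and B3galnt1 (-1.08). Lcn2, Spink8, Jaml and Defb1 were at background in both EtOH groups, Defb1 also in control Dex, and Rnase2a and Rpp25 in dKO EtOH, so the fitted values of these 6 genes depend on levels near background and are not bounds.

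Other splits of the arrays were tried for each count. The 6 arrays of a comparison of 2 groups make 10 splits, too few for a share under 0.05. The real split alone, 1 of 10 in each, gave as many genes: 1706 with Dex in control and 1230 in dKO MEFs, 2234 between genotypes in EtOH and 1662 in Dex, with 0 as the highest of the others each time. For the interaction, 2 of 100 regroupings of the genotypes within treatment gave as many genes as the real one (193). This alone does not exclude chance, since mixing the genotypes adds their difference to the residuals, and all 85 regroupings that mixed them in both treatments gave 0 genes. With the average genotype difference of each gene taken out, 1 of the same 100, the real one, gave as many (highest other 1). The other regroupings still hold the difference in response and the shift of 3 arrays in their residuals. This can lower their counts, so chance is not excluded. With these 3 arrays as a block, 58 genes passed, 37 of them among the 193. In the arrays as measured, the other of the 2 regroupings that reached 193 gave 853 genes. It joined the 3 control EtOH arrays with control_Dex replicate 3 and dKO_Dex replicates 1 and 2, so it kept the genotype difference in EtOH and mixed the genotypes in Dex. Such a count points to a structure of the samples, and with the average genotype difference taken out no regrouping of this kind called a gene. The median over genes that rose was as far from 0 in 86 of 100 regroupings (real distance 0.0095, highest other 0.203), so chance is not excluded. Over genes that fell, it was so in 1 of 100, the real one (0.209). The highest other was 0.17, or 0.152 with the average genotype difference taken out. The regroupings treat the arrays as exchangeable, but the 3 arrays that share a shift lie in control Dex and dKO EtOH only. Chance is therefore not excluded for this median either. The median includes the median difference of all genes (0.08). The part beyond that (0.13) was not regrouped, so for it chance stays open as well.

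Genes that fell with Dex fell less in dKO MEFs (median difference 0.21, against 0.08 over all genes). With the 3 arrays that share a shift as a block the difference to all genes was 0.118. In that fit dKO_EtOH replicate 3 is the only array of its group outside the block, so the fit leans on it. It cannot tell the shift from a difference of that array, so the shift stays open. The tables argue against a floor of signal as the whole cause in these arrays. Among 559 genes that fell and had a mean above log2 9, the difference to all 4668 genes that bright was 0.0991. Its interval over resampled genes, 0.0671 to 0.135, holds the arrays fixed and leaves out the spread between arrays. A dependence on 1 dKO EtOH array stays open, since without dKO_EtOH replicate 3 the difference to all genes was 0.0274, with the 2 shifted arrays left as that group, and with array weights, which were lowest for that array, it was -0.0279. The loss of cryptochromes, the design's own explanation, stays open and untested.

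Clock outputs as a list were not called with Dex in either genotype, but their responses differed (median difference 0.54, a call lost with an estimated correlation, adjusted p = 0.171), and Dbp, Nr1d1, Nr1d2 and Tef fell in control MEFs. With the 3 shifted arrays as a block the median difference was 0.418, which argues against these arrays as the whole cause. A fault of single probes stays open: the only further probe of these genes past the filter, of Nr1d1, gave 1.92 (adjusted p = 0.0525), but it was at background in control Dex and decides nothing. A candidate explanation, which these values do not decide, is that Dex set the phase of a clock that control cells have and dKO cells lack. In control MEFs the positive-arm genes had a median of 0.695, a call lost with an estimated correlation (adjusted p = 0.0748), and the outputs, whose fall prompted the explanation, had -0.35 (adjusted p = 0.159). Nfil3, which rose most on the positive-arm list, also rose in dKO MEFs. With 1 time point per group, a change of phase and a change of level were not separated.

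Macrophage and cartilage genes differed between genotypes, the macrophage list with the preset correlation only. A lower share of macrophages in the dKO cultures fits the macrophage markers, of which 9 of 11 were lower in EtOH and 8 in Dex, although abundant Lyz2 (15.33 in control and 15.14 in dKO EtOH) and Lyz1 were not called, and may be one source of these differences. These same calls prompted the explanation, so they do not test it. For the cartilage genes the tables argue against a lower share of macrophages as the whole cause, since fewer macrophages would raise the genes of all other cells alike: the 23 collagen and matrix genes had an upper quartile of 0.147 over both treatments, and the cartilage genes, with those at background at their bounds, a lower quartile of 0.499. The tables also argue against a lower share of fibroblasts, which would raise the markers of every other cell type, because macrophage markers had -0.690. Near the targeted loci, 13.75% of genes (11 of 80) were called in 1 direction in both treatments. Among other genes it was 10.8% (904 of 8340, Fisher's exact p = 0.369), which argues against these neighbours as a set. Such a share cannot decide on single neighbours, which stay open. Near Cry2, for example, Tspan18 was higher (1.20 in EtOH and 1.73 in Dex), and near Cry1 the growth factor gene Igf1 was lower (-0.58 and -0.73). Spi1, near Cry2, was lower too (-0.91 and -0.86), but it is a gene of myeloid cells, and macrophage markers were lower as well. The genotype itself and differences between the embryos stay open and untested.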

How the results depend on the processing

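The settings with the 3 shifted arrays as a block or left out, and the fits with each gene kept on its probe, were chosen after the data were seen, and all others before. Of 27 settings besides the reported one, an offset of 50, a detection p of 0.05, all probes, and trend and robust variances left every count within 1.5 times its reported value and no median reversed. The fit of only the compared groups, which gives no interaction, left the 4 counts of comparisons of 2 groups and both overlaps within that range. Over all settings, the 37 called list results kept the call and direction of the test in 886 comparisons with the reported value and lost the call in 57. For the 216 gene results named in the text these were 5534 and 9, with 25 that passed only in the alternative and 11 of opposite sign. Settings that leave out arrays or change the values chose the probe of a gene again, and Per2 changed probe in several of them. With each gene kept on its probe the gene results were 5535, 9, 24 and 11 and the list results unchanged in number. Per2 then did not pass in dKO MEFs without control_Dex replicate 3 (0.19) or dKO_EtOH replicate 3 (0.25), nor in the interaction without the latter (0.60, adjusted p = 0.0625), and it passed in control MEFs without control_Dex replicate 3 (-0.48, adjusted p = 0.0196).

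Array weights gave 2824 (Dex in control), 3159 (Dex in dKO), 4146 (genotype in EtOH), 2905 (genotype in Dex) and 1777 (interaction) genes, overlaps of 684 higher and 538 lower, and median differences of 0.14 over induced genes (reversed) and 0.057 over repressed genes, no longer past the test. These weights were lowest for dKO_EtOH replicate 3 (0.238) and control_Dex replicate 3 (0.26). A fold of at least 1.5 left 1021, 771, 1392 and 1017 genes in the 4 comparisons of 2 groups, as it asks for more. The replicate block gave 37 interaction genes, and the block within genotype 32, with 745 for Dex in dKO and an overlap of 172 lower. Interaction counts were 304 without background correction, 697 with median scaling, 323 in the deposited table and 59 without a filter. Median scaling reversed the median over induced genes (0.17). With the 3 arrays as a block, the interaction had 58 genes, genotype in Dex 2512, and the induced median was -0.10, now past the test. Without them, Dex in dKO had 684 genes, genotype in EtOH 1414 and the interaction 67, and the induced median was -0.093, now past the test. Of the interaction genes, 37 and 39 were the same as the 193. The difference in response of Fkbp5 (0.32) was -0.14 without background correction, -0.12 in the deposited table, -0.058 with the block and -0.0247 without the 3 arrays. That of Sgk1 (-0.32) was 0.070 with median scaling, and its genotype difference in EtOH (0.01) was -0.26 with median scaling and -0.0325 with array weights. None of these values passed the test. Interaction calls were lost for Rnase2a without background correction (0.38, adjusted p = 0.0597), for Pdlim4 (1.24, 0.0571) and Aqp1 (-1.40, 0.0593) with the block within genotype, and for B3galnt1 without the 3 arrays (-0.98, 0.0534). The cause was not tested.

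Leaving out 1 array at a time gave 1202 to 1985 (Dex in control), 717 to 2205 (Dex in dKO), 1442 to 3126 (genotype in EtOH), 1146 to 1939 (genotype in Dex) and 30 to 1202 genes (interaction), overlaps of 294 to 441 higher and 198 to 334 lower, and medians of -0.0499 to 0.14 over induced (the highest, without dKO_EtOH replicate 3, reversed and past the test) and 0.13 to 0.26 over repressed genes. Each highest count of called genes came without dKO_EtOH replicate 3. Cry2 changed by -0.0108 to 0.346 with Dex in dKO and differed by -0.0256 to 0.332 between genotypes in Dex, and Sgk1 by -0.0872 to 0.0767 in EtOH, none past the test. A group left with 2 arrays is assumed to vary like the others. The bead chip as a block was not run, as no file names it. Depth on arrays is signal over background: 42.6% to 44.9% of probes were above it.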

Other observations

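The tests on the shift of 3 arrays in this part were chosen after the data were seen.

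Second probes of Per2, Per1 and Tsc22d3 went the same way as the ones used: for Per2 a further probe read 7.55 and 7.31 in control and 9.41 and 9.96 in dKO MEFs (EtOH and Dex), with another probe at background on all 12 arrays. For Per1 it read 6.05, 8.07, 6.86 and 8.57, and for Tsc22d3 6.87, 9.92, 8.87 and 10.37. That of Ciart read 7.49, 7.40, 10.07 and 11.04, so with Dex in control MEFs it went the other way from the one used (7.62 and 7.69). The further probe of Nr1d2 was above background on 2 arrays. The Per3 probe was above background on 2 arrays.

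Some lists split between genotypes without a call. Immediate early and stress genes had 7 of 20 higher and 5 lower in dKO MEFs in each treatment, with medians of -0.01 in EtOH (mean 0.17, adjusted p = 0.235) and 0.00 in Dex (mean 0.09, adjusted p = 0.935). In EtOH the stress gene Trib3 was higher by 1.81 ± 0.14 and Fos lower (-0.94 ± 0.11). Positive-arm clock genes had 2 of 4 higher and 2 lower in EtOH (median -0.19, adjusted p = 0.878) and 1 higher and 2 lower in Dex (median -0.68, adjusted p = 0.0725), Nfil3 among the lower (-1.07 ± 0.11 in Dex). Cholesterol synthesis genes had 4 of 14 higher and 1 lower in EtOH (median 0.08, adjusted p = 0.514), and adipogenesis genes 1 of 12 higher and 3 lower (median -0.04, or -0.10 at the bounds, adjusted p = 0.878). Smooth muscle genes had 2 of 14 higher in each treatment (medians 0.15 and 0.22, adjusted p = 0.19 and 0.153), and hypoxia genes had medians of 0.01 and -0.02.

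The 3 arrays that share a shift stood out within their groups. The SD of the log2 difference between replicates was 0.40 to 0.45 in the pairs that cross the shift and 0.23 to 0.27 in the others. Over 2166 genes with further probes, the shift measured with 1 probe correlated at 0.388 with the shift measured with another, against 0.726 to 0.849 for the 4 comparisons of 2 groups, so it was less shared between probes of a gene than the effects of Dex and genotype were.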
